A study of Mus musculus with 6 samples.

How the data were processed

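Per the labels, epithelial cells were isolated from the small intestine of E18.5 control and Gata4Gata6 double conditional knockout (cKO) mice, total RNA was extracted with a Qiagen RNeasy Mini kit and labelled with biotin by a whole-transcript sense protocol, and 6 Affymetrix Mouse Gene 1.0 arrays were hybridised, 3 per group. The cre driver, the deleted exons and the litters are not given in the sources used here, nor is it stated that the arrays of a group held RNA of separate animals.

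The values analysed are 1 deposited log2 level per probe set and array, 35512 probe sets on 6 arrays, which the authors made with dChip, per the series text. The dChip version, its background correction, its normalization between arrays and its expression model are not given in the sources used here. The scale was read from the values, which run from 0 to 14.25 as log2 levels of scanner intensities do, so a fold change here rests on a log base that no label states. Centring is unknown, and array medians were 7.73 to 7.84. The values have 2 decimals. Scanner files and detection calls were not used here, so no probe set could be called above or below background, and low levels can hide larger changes. Between 117 and 179 values per array were exactly 0, of which 19 values in 13 genes entered the tests.

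Gene names came from the platform annotation paired with the probe sets, in which 21789 probe sets have 1 gene, 1621 have several and 12102 have none. Symbols were looked up by gene ID in a RefSeq gene table of GRCm38.p6, where 21698 matched, 91 did not and 0 changed. The build behind the array annotation is not given in the sources used here, so no coordinates are printed. Only probe sets with 1 gene were tested, and of the 999 genes with several such probe sets the one with the highest mean over the 6 arrays was kept, which left 19938 genes. A probe set sums probes along a gene and cannot separate its transcripts or near-identical copies.

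Groups were taken from the source names given with the samples. The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. Levels were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 with no covariate, no further normalization and no filter on dim genes, and p-values were adjusted by Benjamini-Hochberg over all genes at a threshold of 0.05. A fold change is 2 to the power of the log2 change. The 45 lists comprised 25 of gut functions, 11 of other cell types and of tissue handling, and 9 gene families, each named where its result is given. Each was tested against all other genes with camera at its preset correlation of 0.01 and again with an estimated correlation. With fry each was tested for a shift from no change, without comparison to other genes. All were adjusted over the 45 lists. Members were also adjusted over the list alone. A further 3 lists were written after the first results had been seen and were adjusted among themselves.

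The genes named are Gata4 and Gata6, the 10 largest rises and 10 largest falls among genes past the threshold without clone-like or predicted names, up to 4 members of each list with the smallest adjusted p, a set of 18 genes named in advance whether changed or not (among them Lct, Fabp6, Muc2, Chga and Lgr5), and sex-linked transcripts as a check of the animals. Other genes are said to be named after their values were seen. This gave 205 genes, 127 of them past the threshold.

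The replicate files were compared before use, and no 2 arrays held the same values. The procedure was tested on simulated data with the levels and spreads of these arrays and 19938 genes. Of genes changed by a log2 of 0.5, 1, 2 and 4, with 50 genes of each size, it recovered 36%, 60%, 96% and 98%. Of its 153 calls 5.23% were false. More genes passed in the real comparison, and the adjusted p depends on how many genes change, so these recovery shares need not hold there. Of 500 random lists, 3.6% had a camera p under 0.05 with the preset correlation and 0.2% with an estimated one. The simulated genes were drawn independently, whereas members of a real list, or many genes of an array, can move together. On these arrays the estimated correlation ran from −0.13 (mesothelial list) to 0.96 (pancreatic list). The 2 shares therefore do not show how either test behaves with correlated lists.

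Alternatives planned in advance were quantile normalization, centring of each array on its median, log2(value + 32), leaving out the dimmest genes by mean level at either of a pair of limits (lower tertile, median), a trended and robust eBayes, array weights, the replicate number as a block, the mean of all probe sets of a gene, every probe set, removal of the sex-linked transcripts, and each array left out in turn. Added after seeing the data were a fit without control 3 and cKO 2, and a fit with the mean level of the hepatocyte and erythroid lists as a covariate. The labels give no scan date or batch, so none could be tested.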

Results

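RNA from isolated epithelial cells of the mouse small intestine at E18.5 (days of embryonic development) was measured on 6 whole-transcript arrays. Per the labels, 3 arrays held control RNA and 3 held RNA of Gata4Gata6 double conditional knockout (cKO) mice. GATA4 and GATA6 are zinc finger transcription factors of the gut endoderm, and the series asks how gene expression in this epithelium differs when both are absent. The deposited levels are on a log2 scale, and the median over all probe sets lay between 7.73 and 7.84 on the 6 arrays. The number of arrays limits the precision. The labels do not state that the arrays of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical. All changes below are the arrays labelled cKO minus the arrays labelled control, as log2 change ± SE with n = 3 arrays in each group, and an adjusted p is limma's with Benjamini-Hochberg adjustment over 19938 genes.

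The 2 targeted genes were not lower on the arrays labelled cKO. Gata4 (probe set 10420747) stood at 10.95 ± 0.015 (SD, n = 3) on the control arrays and at 11.41 ± 0.087 on the arrays labelled cKO, a change of 0.47 ± 0.075 (adjusted p = 0.0101). Gata6 stood at 12.26 ± 0.026 and 12.71 ± 0.017, a change of 0.45 ± 0.065 (adjusted p = 0.0067). Both genes were higher on all 3 arrays labelled cKO than on any control array. This direction goes against a loss of the 2 transcripts, and every direction below rests on the labels alone. A probe set of this array design sums probes along the whole gene, each of the 2 genes has 1 probe set, and the deleted parts are not given in the sources used here, so signal from exons outside a deletion would be counted too. The related Gata5 changed by −0.09 ± 0.089 (adjusted p = 0.585; −0.13 to −0.03 with 1 array left out). With control 3 and cKO 2, the pair of arrays described next, both left out, the Gata4 change was 0.49 (adjusted p = 0.0647) and the Gata6 change was 0.47 (adjusted p = 0.0503).

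A pair of arrays differed from the others of their group in ways the labels do not explain. On cKO 2 the hepatocyte list averaged 12.7, against 8.73 and 8.79 on the other arrays labelled cKO and 10.01, 8.56 and 11.2 on the controls. Its erythroid list averaged 9.86, against 6.96 and 7.19 on the other arrays labelled cKO and 8.06, 7.25 and 8.16 on the controls. The immune and endothelial lists were also highest on cKO 2, at 9.52 and 8.82, against at most 8.18 and 8.22 on the other 5 arrays. Across genes, which are not independent replicates, cKO 2 correlated with cKO 1 and cKO 3 at r = 0.956 and 0.955, while those 2 correlated at r = 0.988. With controls 1 and 2, cKO 1 and cKO 3 correlated at r = 0.961 to 0.964, and with control 3 at r = 0.953 and 0.954. Control 3 was the only array with a male pattern of sex-linked transcripts. Its level of Xist, the RNA that silences an X chromosome in females, was 6.18 against 11.74 to 12.42 on the other 5 arrays. The Y-linked Eif2s3y was at 9.36 on control 3 and at 4.49 to 4.86 elsewhere, and Kdm5d and Uty were also highest there, at 8.58 and 8.02.

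Of the 19938 genes tested, 2580 changed between the groups, 1101 of them higher and 1479 lower on the arrays labelled cKO. A change of at least 2-fold was reached by 722 of these genes, 355 higher and 367 lower. All 2580 genes had non-overlapping groups, as had 6496 genes in all (32.6%), where chance gives 10%. The first principal component held 51.0% of the variance and separated the groups, with cKO 2 at 48.6 and cKO 1 and cKO 3 at 21.6 and 22.2. The next held 29.8% and mainly set cKO 2 (38.6) apart from cKO 1 and cKO 3 (−28.4 and −30.1). The controls lay between them, at 6.84, −5.19 and 18.3. Fewer genes passed with 1 array left out: 1482 without control 2, 1514 without control 3 and 1587 without cKO 3. With both control 3 and cKO 2 left out, 1586 genes passed, 708 of them higher and 878 lower.

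The largest rise on the arrays labelled cKO was that of Cyp2j5, a cytochrome P450 epoxygenase, by 5.45 ± 0.18 (43.6-fold, adjusted p = 6.59e-05). Fabp6, the ileal bile acid binding protein, rose 32.8-fold, and Reg3b, an antimicrobial lectin, rose 26.2-fold. Next came Slc5a8, a monocarboxylate transporter (23.2-fold), the beta-defensin gene Defb37 (22.2-fold), Tmigd1 (log2 change 4.17), the bile acid transporter gene Slc10a2 (17.3-fold), Fa2h, a fatty acid 2-hydroxylase (14.03-fold), the amino acid transporter gene Slc6a14 (13.3-fold) and Car1, carbonic anhydrase 1 (10.9-fold). The largest fall was that of Lct, the lactase gene, from 13.15 ± 0.13 to 8.61 ± 0.96 (SD, n = 3), a change of −4.54 ± 0.45 (23.3-fold lower, adjusted p = 0.00163). The others among the 10 largest falls were Mfsd2a, a lysophospholipid transporter (16.6-fold lower), Sult6b2 (15.3-fold), Slc37a2 (12.6-fold), Gda, guanine deaminase (12.6-fold), Asah2, neutral ceramidase (11.7-fold), Slc9a3, the brush border sodium/proton exchanger (11.5-fold), Tdrp (10.1-fold), Btnl1 (10.1-fold) and Sema7a (9.49-fold). All 20 kept their call with each array left out in turn.

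**Figure D1:**
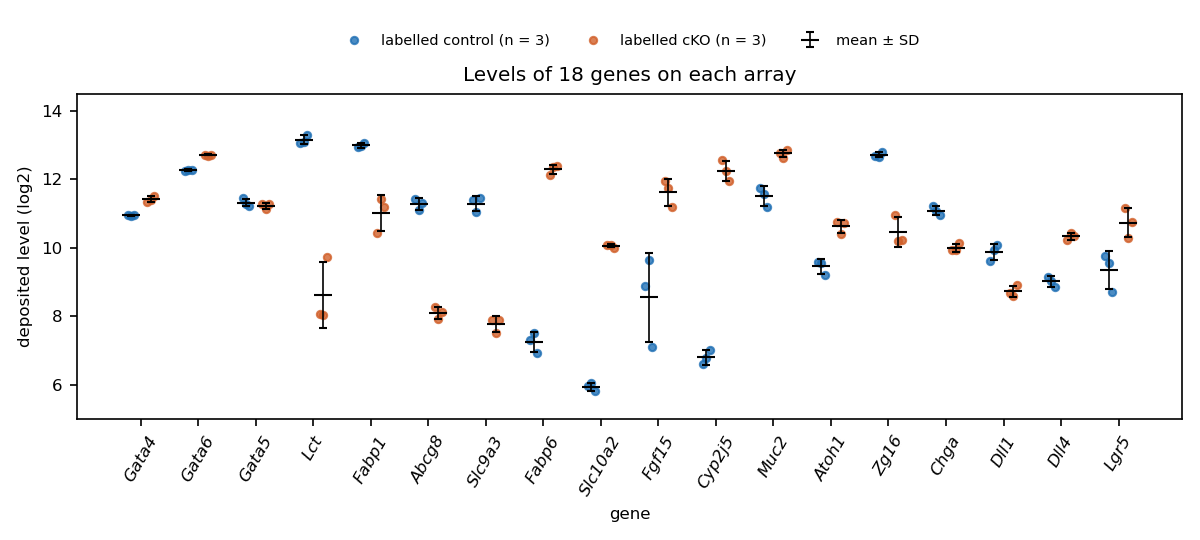
Deposited levels (log2, vertical axis) of 18 genes (horizontal axis) on the 3 arrays labelled control and the 3 labelled cKO; points are arrays, and black bars are the group mean ± SD. Gata4 and Gata6 lie slightly higher on the arrays labelled cKO (changes of 0.47 and 0.45), Lct falls by 4.54, and Fabp6 and Slc10a2 rise by 5.04 and 4.12.

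Genes that take up and package dietary lipid fell together. Of 20 measured genes of lipid absorption and lipoprotein assembly, 19 were lower on the arrays labelled cKO and 0 were higher, and the list median was −1.58 (camera adjusted p = 6.04e-19; adjusted p = 0.17 with an estimated correlation). The sterol exporter genes Abcg8 and Abcg5 changed by −3.17 ± 0.13 and −3.02 ± 0.14, Creb3l3, a transcription factor of lipid metabolism, by −2.67 ± 0.14, and Dgat1, which makes triglyceride, by −1.81 ± 0.10. Genes typical of proximal enterocytes fell as well, 8 of 11 measured with 0 higher and a median of −1.31 (camera adjusted p = 1.41e-05; adjusted p = 0.173 with an estimated correlation). Besides Lct these included Cybrd1, a ferric reductase (−2.58 ± 0.13), Fabp1, the liver-type fatty acid binding protein (−1.98 ± 0.25), Rbp2, which carries retinol (−1.57 ± 0.08), and Apoc3, an apolipoprotein (−1.03 ± 0.12). Adjusted over the list alone, 20 and 8 genes of the 2 lists were lower. These lists share genes with each other and with lists below, so their shifts are not independent. Fabp1 and Apoc3 are in both, Lct is also a brush border hydrolase and Rbp2 also a retinoid gene. Further falls of the proximal list are counted again among the lipid or transporter genes. In fatty acid oxidation and ketogenesis 6 of 18 genes fell and 0 rose (median −0.26, camera adjusted p = 0.00373; adjusted p = 0.728 with an estimated correlation), and 7 fell adjusted over the list alone. Acot1 and Acot2, acyl-CoA thioesterases, fell by 1.19 ± 0.13 and 0.73 ± 0.09. This count was 2 without control 2, without control 3 or without cKO 3, and 3 without cKO 1. In cholesterol synthesis 1 of 18 genes changed, also when adjusted over the list alone: Insig1, a feedback regulator of the pathway, fell by 1.11 ± 0.19 (adjusted p = 0.0118). The shift of this list did not pass (median −0.17, camera adjusted p = 0.253) except without cKO 1 (0.0426), the median was −0.07 without cKO 3, and the Insig1 call was lost without control 2 or control 3 (adjusted p up to 0.0534). Without cKO 2 the lower count was 2.

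Digestive enzymes and transporters of the brush border were mostly lower. Of 16 brush border hydrolases 9 fell and 1 rose on the arrays labelled cKO, the same counts as adjusted over the list alone (median −0.65, camera adjusted p = 0.000508; adjusted p = 0.728 with an estimated correlation). Mme, neprilysin, fell by 2.08 ± 0.15 and the alkaline phosphatase gene Akp3 by 0.86 ± 0.09, while Xpnpep2, an aminopeptidase, rose by 2.11 ± 0.11. Alpi, the main intestinal alkaline phosphatase gene, changed by −0.53 ± 0.10 (adjusted p = 0.0152), a call lost without any 1 control array or without cKO 3 (adjusted p up to 0.0616). Of 22 nutrient and mineral transporters 14 fell and 2 rose, with 16 lower adjusted over the list alone (median −0.75, camera adjusted p = 8.6e-06; adjusted p = 0.692 with an estimated correlation). By adjusted p the falls began with Slc9a3, the amino acid transporter gene Slc7a8 (−0.90 ± 0.09), the fructose transporter gene Slc2a5 (−1.63 ± 0.17) and the sodium-glucose transporter gene Slc5a1 (−0.75 ± 0.08). The 2 rises, named after their values were seen, were S100g, a calcium-binding protein (0.78), and Slc1a1, a glutamate transporter (1.63). Without control 1 or without control 3 the lower counts were 5 hydrolases and 9 transporters. Of 12 genes of microvillus structure 4 fell, with 5 lower and 1 higher adjusted over the list alone (median −0.26, camera adjusted p = 0.0426; adjusted p = 0.814 with an estimated correlation). That list kept 0 calls without control 2, control 3 or cKO 3, 1 without cKO 2 and 2 without control 1, and its shift did not pass without cKO 2 (camera adjusted p = 0.159), control 3 (0.113), control 1 (0.0571) or cKO 3 (0.0514).

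Genes of ileal bile acid handling moved the other way. Of 8 measured, 5 rose and 1 fell on the arrays labelled cKO, also when adjusted over the list alone (median 0.74, camera adjusted p = 0.0013; adjusted p = 0.39 with an estimated correlation). Fabp6 rose by 5.04 ± 0.16 and Slc10a2, the apical sodium-bile acid transporter, by 4.12 ± 0.086, from a mean of 5.94 on the control arrays. Slc51b and Slc51a, which together form the basolateral exporter, rose by 0.78 ± 0.09 and 0.69 ± 0.08. Fgf15, the ileal hormone that limits bile acid synthesis, rose by 3.07 ± 0.62 (adjusted p = 0.0241), with a call lost without control 1, cKO 1 or cKO 3 (adjusted p up to 0.0741). The gene that fell, named after its values were seen, was Nr0b2, a nuclear receptor that represses bile acid synthesis (−0.54), and its call was lost without control 2, control 3 or cKO 3. Endocytic and lysosomal genes of neonatal ileal enterocytes did not pass as a list (1 higher and 3 lower of 10, also when adjusted over the list alone; median −0.28, −0.42 to −0.18 with 1 array left out, camera adjusted p = 0.185). Among them the endocytic receptor gene Lrp2 rose by 1.87 ± 0.22, and the lysosomal genes Ctsl, Glb1 and Ctsz fell by 1.65 ± 0.16, 0.74 ± 0.09 and 0.73 ± 0.09. Neither the stomach list nor the colon list passed. Of 16 gastric genes 1 rose (median −0.03, −0.13 to 0.02 with 1 array left out, camera adjusted p = 0.939), and of 10 colonic genes 1 rose (median −0.07, −0.12 to −0.0075 with 1 array left out, camera adjusted p = 0.939). Adjusted over the list alone the gastric count was again 1, and 2 colonic genes were higher and 1 lower. The gastric gene was Vsig1 (1.25 ± 0.25, adjusted p = 0.0242), a call lost on leaving out any array but cKO 1 (adjusted p up to 0.0927), and the colonic gene was Car1. Without control 2 or cKO 2 the higher colonic count was 2, and a lower gastric gene passed without control 1 or control 3, as did a lower colonic gene without cKO 1 or cKO 2. The mean of each list was above 0 (0.03 and 0.29), against the sign of its median.

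**Figure D2:**
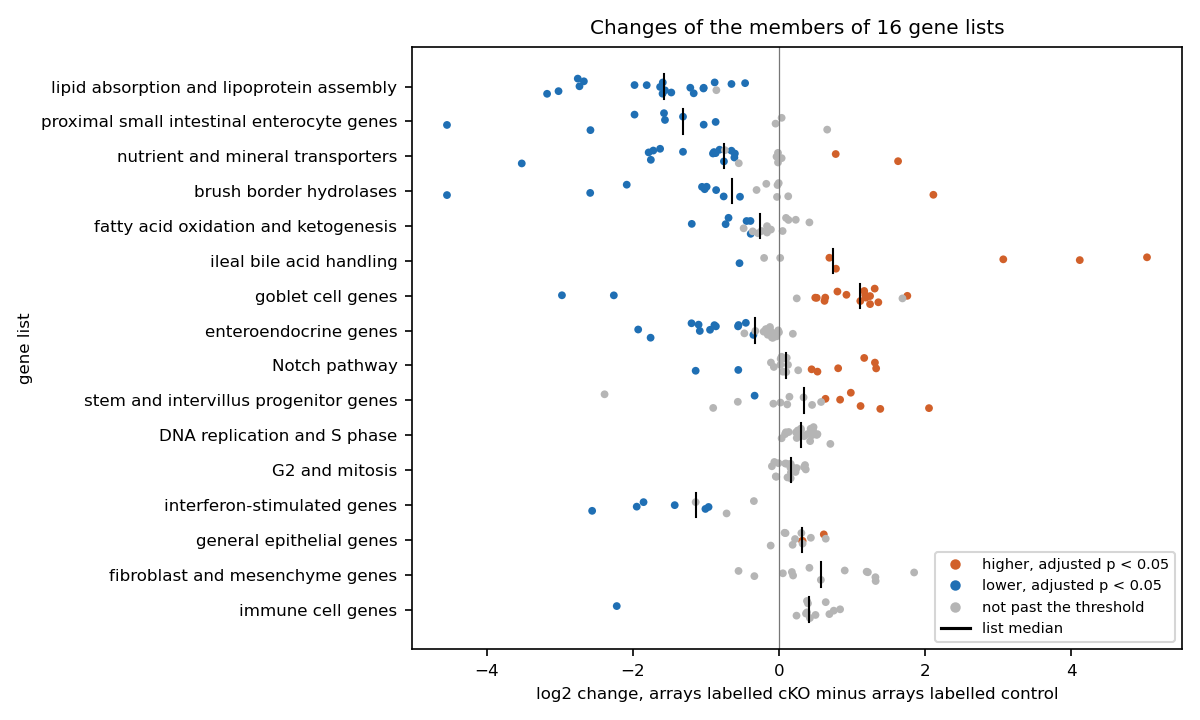
Log2 change (horizontal axis, arrays labelled cKO minus arrays labelled control, n = 3 each) of every measured member of 16 gene lists (vertical axis); each point is a gene, coloured where its adjusted p passed the threshold, and black lines are list medians. The lipid absorption list has a median of −1.58 with 19 of 20 members lower, and the goblet cell list a median of 1.11 with 15 of 19 members higher.

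Goblet cell and enteroendocrine genes moved in different directions, and the tuft and Paneth lists did not pass. Of 19 goblet cell genes 15 rose and 2 fell on the arrays labelled cKO, also when adjusted over the list alone (median 1.11, camera adjusted p = 3.93e-09; adjusted p = 0.517 with an estimated correlation). Muc2, the main gel-forming mucin of the gut, rose by 1.25 ± 0.15, Atoh1, the secretory fate determinant, by 1.17 ± 0.15, the transcription factor genes Creb3l1 and Foxa3 by 1.76 ± 0.18 and 1.11 ± 0.11, and Guca2a, guanylin, by 0.92 ± 0.09. The falls were Zg16, a lectin of goblet cell granules (−2.26 ± 0.21), and St6galnac1, a mucin sialyltransferase named after its values were seen (−2.97). Of 27 enteroendocrine genes 12 fell and 0 rose, also when adjusted over the list alone (median −0.32, camera adjusted p = 9.6e-06; adjusted p = 0.517 with an estimated correlation). Chga, chromogranin A, fell by 1.08 ± 0.10, and the peptide hormone genes Tac1, Cck and Pyy by 1.76 ± 0.18, 1.20 ± 0.15 and 0.94 ± 0.11. Neurog3, which sets the endocrine fate, changed by −0.47 ± 0.17 and did not pass (adjusted p = 0.132) except without cKO 3, where it was lower. The endocrine count was 5 without control 1 or control 2, and 7 without control 3 or cKO 1. Tuft cell genes did not pass as a list (2 higher and 1 lower of 12, also when adjusted over the list alone; median −0.02, −0.06 to 0.04 with 1 array left out, mean 0.26, camera adjusted p = 0.854). Rgs13, a tuft cell regulator of G protein signalling, rose by 1.91 ± 0.21 from a low level of 4.33. The lower count of this list was 0 on leaving out any array, and the higher count was 1 on leaving out any array but cKO 1. Paneth cell and antimicrobial genes did not pass as a list either (1 higher and 2 lower of 11, also when adjusted over the list alone; median 0.09, 0.055 to 0.15 with 1 array left out, camera adjusted p = 0.88). Beside the rise of Reg3b, its relative Reg1 fell by 2.87 ± 0.20 and the alpha-defensin gene Defa24 by 1.39 ± 0.14.

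Several progenitor and Notch genes rose. Of 17 genes of stem cells and intervillus progenitors 6 rose and 1 fell, with 8 and 4 adjusted over the list alone (median 0.34, camera adjusted p = 0.0438; adjusted p = 0.814 with an estimated correlation). Cd44, a surface receptor of intestinal progenitors, rose by 2.05 ± 0.18, and its call stayed with each array left out in turn. Lgr5, the stem cell receptor, changed by 1.39 ± 0.33 (adjusted p = 0.0405), a call lost on leaving out any array but cKO 2 (adjusted p up to 0.111). Olfm4, another stem cell gene, changed by −2.39 ± 0.80 and did not pass (adjusted p = 0.114) except without cKO 2, and its change ran from −3.25 to −1.55 with 1 array left out. The higher count was 2 without control 2 and 1 without cKO 1 or cKO 3, the lower count was 2 without control 3 or cKO 2 and otherwise 0, and the list's shift did not pass without control 3, cKO 1 or cKO 3 (camera adjusted p of 0.113, 0.0803 and 0.0653). Of 19 Notch pathway genes 6 rose and 2 fell, also when adjusted over the list alone (median 0.10, camera adjusted p = 0.0218; adjusted p = 0.517 with an estimated correlation). The ligand gene Dll4 rose by 1.31 ± 0.11 and Lfng, a glycosyltransferase that modifies Notch, by 1.33 ± 0.15, while the ligand gene Dll1 fell by 1.14 ± 0.14. Atoh1, named above, is also among the 6 rises, and these counts do not show whether Notch signalling rose or fell. The shift of this list did not pass without control 3 (median 0.05, camera adjusted p = 0.0546). All 21 genes of DNA replication and S phase had a change above 0, but 0 passed on their own under limma, also when adjusted over the list alone, and 6 had an unadjusted p under 0.05 (median 0.30, camera adjusted p = 0.000386; adjusted p = 0.814 with an estimated correlation). That shift did not pass with control 3 and cKO 2 both left out (median 0.15, camera adjusted p = 0.105), and without cKO 1 the median was 0.52 with 1 gene past. Of 19 genes of G2 and mitosis 0 passed under limma, also when adjusted over the list alone or at an unadjusted p under 0.05, and the shift did not pass (median 0.16, camera adjusted p = 0.141), although it did without control 1 (0.012) or cKO 1 (median 0.29, 0.00105). The median was 0.03 without control 3 or without cKO 2. Mki67, the proliferation marker, changed by 0.37 ± 0.32 (adjusted p = 0.524; 0.03 to 0.66 with 1 array left out). In the Wnt pathway 2 of 18 genes rose, also when adjusted over the list alone (median 0.01, −0.04 to 0.02 with 1 array left out, camera adjusted p = 0.711). They were Ccnd1, cyclin D1 (1.25 ± 0.17), and Wnt5a (1.16 ± 0.23), whose call was lost without any 1 control array or without cKO 3 (adjusted p up to 0.0848). In the Hedgehog pathway 3 of 9 genes rose, also when adjusted over the list alone, and the shift did not pass (median 0.10, camera adjusted p = 0.0638), although it did without control 2 (0.0457). The median ran from 0.055 without control 1 to 0.26 without cKO 3. The receptor gene Ptch1 rose by 0.56 ± 0.08 and was the only call of the list without control 2, control 3 or cKO 1, and 2 passed in the other fits with 1 array left out.

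Among 23 intestinal transcription factors 5 rose and 3 fell, with 7 and 4 adjusted over the list alone. The list did not pass (median 0.11, 0.055 to 0.17 with 1 array left out, camera adjusted p = 0.0638), although it passed without control 1 (0.0288) or cKO 2 (0.0414). Foxa1, a forkhead factor, rose by 1.58 ± 0.15 and Pparg, a nuclear receptor of fatty acid signalling, 2.82-fold, beside Foxa3 above, and Creb3l3 fell. The lower count was 1 without any 1 control array or without cKO 3. The main regulators of intestinal identity did not pass: Cdx2 changed by 0.11 ± 0.10 (adjusted p = 0.551), Hnf4a by 0.01 ± 0.07 (adjusted p = 0.968) and Pdx1 by 0.20 ± 0.17 (adjusted p = 0.535). With 1 array left out they ran from 0.03 to 0.18, −0.02 to 0.03 and 0.06 to 0.34. Retinoid metabolism did not pass as a list (0 higher and 3 lower of 13, also when adjusted over the list alone; median 0.01, −0.05 to 0.04 with 1 array left out, mean −0.38, camera direction lower, adjusted p = 0.239). Within it Lrat, which stores retinol as retinyl ester, fell by 2.63 ± 0.09, beside Rbp2. In xenobiotic metabolism 3 of 17 genes rose and 5 fell, with 4 and 6 adjusted over the list alone (median −0.09, from −0.25 without cKO 2 to 0.04 without control 3; camera adjusted p = 0.711). The efflux transporter gene Abcb1a rose by 1.81 ± 0.12 and the glutathione transferase gene Gsta4 by 1.61 ± 0.15, while Gstm3, another glutathione transferase gene, fell by 1.40 ± 0.13. This lower count was 2 without control 3, and 3 without control 2 or cKO 3. The higher count was 2 without any 1 array.

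Interferon-stimulated genes were lower on the arrays labelled cKO. Of 9 measured, 6 fell and 0 rose, with 7 lower adjusted over the list alone (median −1.14, camera adjusted p = 9.6e-06; adjusted p = 0.517 with an estimated correlation). The antiviral genes Ifit2 and Ifit1 fell by 1.95 ± 0.16 and 1.85 ± 0.25, and the transcription factor genes Irf1 and Stat2 by 1.01 ± 0.09 and 0.96 ± 0.11. Immediate early and heat shock genes, which respond to the handling of tissue, did not pass as a list (2 higher and 0 lower of 13, also when adjusted over the list alone; median 0.06, 0.015 to 0.14 with 1 array left out, camera adjusted p = 0.185). Hspb1, a small heat shock protein, rose by 0.88 ± 0.11. The higher count was 1 on leaving out any array but cKO 3, and 1 gene was lower without cKO 1.

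Markers of the epithelium and of other cells were compared in the same fit. Of 12 general epithelial genes 3 rose, with 6 adjusted over the list alone (median 0.31, camera adjusted p = 0.000851; adjusted p = 0.723 with an estimated correlation). Krt19 rose by 0.61 ± 0.09, and it was the only call of this list on leaving out any array but cKO 2, without which 4 passed. Of 13 fibroblast and mesenchyme genes 0 passed under limma, with 7 at an unadjusted p under 0.05 and 4 higher and 2 lower adjusted over the list alone (median 0.57, camera adjusted p = 0.0379; adjusted p = 0.814 with an estimated correlation), and 3 rose without cKO 3. Vim, vimentin, changed by 1.32 ± 0.35 and Dcn, decorin, by 1.85 ± 0.49 (adjusted p of 0.0578 and 0.058), and both passed without cKO 3. The list's shift did not pass without control 2 (camera adjusted p = 0.115) or cKO 1 (0.113), and its median was 0.30 without cKO 2. Smooth muscle genes did not pass as a list (1 higher and 1 lower of 10; median 0.57, camera adjusted p = 0.074) but passed without cKO 3 (camera adjusted p = 0.000892), where 5 were higher. The higher call was that of Actg2, a smooth muscle actin (1.85 ± 0.46, adjusted p = 0.0475), lost on leaving out any array but cKO 3 (adjusted p up to 0.145), and 2 genes were lower without cKO 1. Mylk, a myosin light chain kinase, fell by 1.11 ± 0.14. Immune cell genes did not pass as a list (0 higher and 1 lower of 12; median 0.41, camera adjusted p = 0.298), but did without cKO 3 (median 0.79, camera adjusted p = 0.0478), and their median was −0.12 without cKO 2. The gene that fell was Csf1r, the macrophage growth factor receptor (−2.22 ± 0.40), a call lost without any 1 control array or without cKO 1 (adjusted p up to 0.0646). Of 5 mesothelial genes 3 rose and 1 fell, Upk1b by 1.40 ± 0.13 and Upk3b by −1.86 ± 0.24 (median 0.77, camera adjusted p = 0.0581), and the shift passed without control 2 (0.0473) or cKO 2 (0.0361). Enteric neuron and glia genes did not pass as a list (0 higher and 1 lower of 9; median −0.05, −0.09 to −0.03 with 1 array left out, camera adjusted p = 0.53), and Ret, a receptor of enteric neurons, fell by 1.40 ± 0.20. In that list 1 was higher without cKO 1, and 2 were lower without cKO 3. Under limma 0 genes passed among 11 endothelial genes (median 0.01, from −0.21 without cKO 2 to 0.37 without cKO 3, camera adjusted p = 0.819), 7 erythroid genes (median 0.25, 0.711), 9 pancreatic genes (median 0.83, 0.141) and 9 hepatocyte genes (median 0.66, 0.489). At an unadjusted p under 0.05 the counts were 0, 0, 0 and 1. Without cKO 2 the hepatocyte and erythroid medians were −0.73 and −0.74, and without control 2 they were 0.07 and −0.04, with up to 1.14 and 0.77 without cKO 1. The pancreatic list averaged 10.7, 9.07 and 7.66 on controls 1 to 3, and its shift passed without control 1 (median 1.83, camera adjusted p = 0.000274), while its median was 0.10 without control 3. Adjusted over the list alone, 4 smooth muscle genes were higher and 2 lower, 2 neuron and glia genes were lower, and the other counts of these lists were as given.

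**Figure D3:**
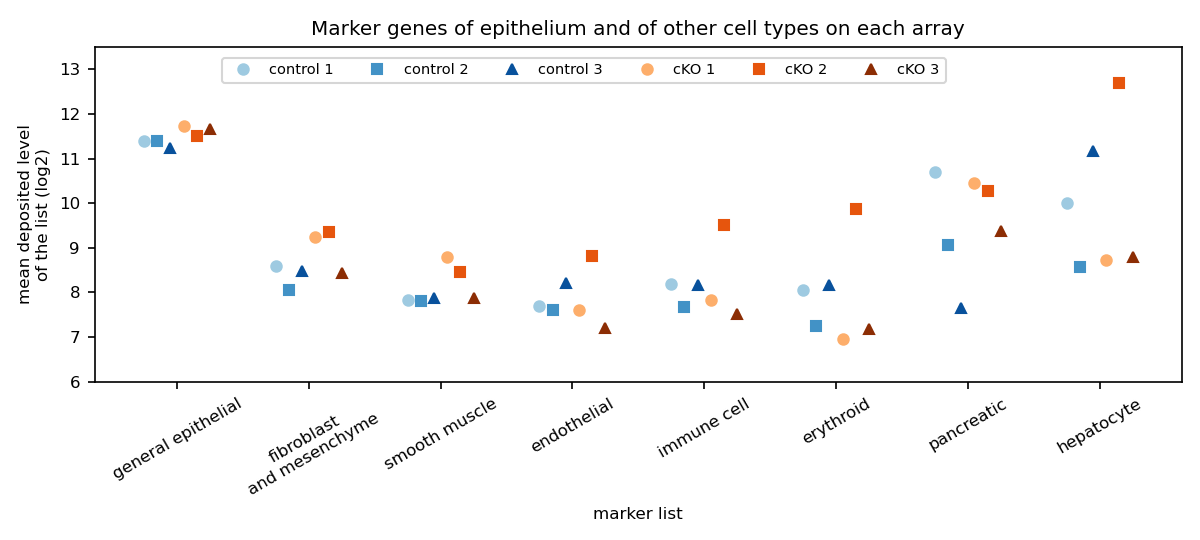
Mean deposited level (log2, vertical axis) of 8 marker lists (horizontal axis) on each of the 6 arrays. The hepatocyte list lies at 12.7 on cKO 2 and between 8.56 and 11.2 on the other 5 arrays, and the general epithelial list lies between 11.2 and 11.7 on all 6.

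Over the 45 lists fixed in advance, 17 passed with camera's preset correlation, 8 higher and 9 lower. With a correlation estimated from these arrays 0 lists passed, the smallest adjusted p being 0.17, and 3 had an unadjusted p under 0.05. On simulated lists of independent, unchanged genes that form of camera was strict, with 0.2% at a p under 0.05. A list short of it is therefore not shown to be unshifted. With fry, which tests whether a list's genes move one way on balance and does not compare them with other genes, 14 lists passed and 20 had an unadjusted p under 0.05. The lists of retinoid metabolism, the Hedgehog pathway and mesothelium passed with fry (adjusted p of 0.017, 0.0213 and 0.00714) and not with camera. The microvillus, stem cell, S phase, fibroblast, ribosomal and complex I lists passed with camera and not with fry.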

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

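The tests of array-wide scaling, of probe sets per gene, of exchanged labels, of RNA from liver and blood, and of immune cells were chosen only after the result was seen.

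Probe sets that the comparisons above leave out also differed between the groups. Of 12102 probe sets with no gene name, 127 were higher and 249 lower on the arrays labelled cKO, 55 and 97 of them by at least 2-fold. Of 1621 probe sets that name several genes, 9 were higher and 42 lower, 3 and 19 of them by at least 2-fold.

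Gata4 and Gata6 were higher, by 0.47 and 0.45, on the arrays labelled as lacking them. A shift of all deposited levels alike is argued against, since the median change of all genes was −0.013 and lay more than 2 SE below both changes. That median does not cover a bias that depends on the level, and after quantile normalization the changes were 0.55 and 0.57. Signal from parts of the genes outside the deletion could hide a loss, but with 1 probe set per gene this cannot be told apart from a true rise of the transcripts. An exchange of all control with all cKO labels cannot be told apart either, because it would turn the sign of every change at once, including the proximal enterocyte median of −1.31. It is background knowledge that loss of GATA4 in the mouse jejunum lowers Lct and raises ileal bile acid genes, the direction seen under the labels as given, but no value in these tables decides it.

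Among the arrays labelled cKO, cKO 2 stood apart. Of the 16 measured members of the hepatocyte and erythroid lists, 15 (93.8%) were higher there than on both other arrays labelled cKO, against 34.8% of all genes. Alb, albumin, named after its values were seen, was at 13.7 on cKO 2, and also at 13.2 on control 3 and 12.04 on control 1. The levels of these lists had already set that array apart, so the count restates them and leaves open whether RNA from liver and blood cells is the source. Of the 16 members, 2 lay in the upper quartile of levels on all 6 arrays. A test of the scaling of that array, also chosen after the result was seen, was dropped, since a correlation hardly changes with the scale of an array. No biological explanation was tested.

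Interferon-stimulated genes had a median change of −1.14 on the arrays labelled cKO. The immune list had a median of 0.41 with all arrays and of −0.12 without cKO 2 (SD of its members 0.78), while the interferon list then stood at −1.60. These values cannot decide whether fewer immune cells were the whole source. The immune list averaged 9.52 on cKO 2, against 7.82 on cKO 1 and 7.52 on cKO 3, which raised its median with all arrays. Some members were dim, such as Ptprc and Mrc1 (6.95 and 7.14 on the control arrays), where a fall could be partly hidden, though no background level is known here. Csf1r, a brighter member (10.39), fell by 2.22, alone among the immune genes. The single array with a male pattern, control 3, is argued against, since without it the interferon median was −1.03 and 5 of the 6 calls stayed. A litter or housing difference that follows the groups stays open, as the labels give neither, and so does the genotype as labelled. The list did not pass with an estimated correlation (adjusted p = 0.517).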

How the results depend on the processing

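The fit without control 3 and cKO 2 and the fit with a liver and blood covariate were chosen after seeing the data. The fit of every probe set and the fit without sex-linked transcripts gave only a total count. No named gene or list past its threshold changed sign under the other alternatives, and of all 2580 calls 1 did, with the mean of all probe sets of a gene. The count of changed genes lay between 2306 (quantile normalization) and 3013 (array weights) under the planned settings that keep all arrays, test 1 value per gene and add no block. With every probe set tested instead, the count was 2284, which rests on a different set of tests. With 1 array left out and fewer samples fitted, 629 to 959 genes were higher and 844 to 1322 lower. The count of changed genes then ran from 1482 (without control 2) to 2281 (without cKO 2). It fell by over 1.5 times without control 2, control 3 (1514) or cKO 3 (1587), and the lower count also without control 1 (975). With control 3 and cKO 2 both left out 1586 genes passed, 708 higher and 878 lower. The replicate block left 1449 genes, 622 higher and 827 lower. Deviations from the group means correlated across genes at r = −0.02, −0.43 and −0.18 for same-numbered arrays. For differently numbered arrays r ran from −0.30 to 0.36. Since the deviations of 3 arrays sum to 0 in each group, these values can neither show nor exclude a pairing by number. With the block the Gata4 change was 0.47 with an adjusted p of 0.0521, and the cause was not tested. With control 3 and cKO 2 left out, Gata4 changed by 0.485 (adjusted p = 0.0647) and Gata6 by 0.465 (adjusted p = 0.0503) on fewer samples. Over the alternatives in which they were recomputed, the adjusted p of Gata4 ran from 0.00273 to 0.0647 and that of Gata6 from 0.000672 to 0.0503. With an estimated correlation 0 lists passed. Calls of the microvillus, stem cell, Notch, fibroblast and S phase lists were lost under some settings, and those of the other 12 lists under that correlation or under fry only. Other lists passed only under some settings: intestinal transcription factors with quantile normalization (camera adjusted p = 0.0226), centring (0.0498), array weights (0.0355) and the block (0.0426), mesothelial genes with centring (0.0249), the block (0.0479) and the covariate (0.0446), pancreatic genes with centring (0.0486) and the block (0.0109), smooth muscle genes with centring (0.0235), immune cell genes with the covariate (0.0194), and keratins and retinoid genes with the genes below the median level left out (0.0447 for both). Of 127 named genes past the threshold, 91 stayed past it with each array left out. Some changes near 0 that did not pass, such as that of Hnf4a, changed sign and stayed short of the threshold. The lack of detection calls limits what low levels can show.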

Other observations

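The tests of LXR and PPAR gamma targets and of antigen processing were stated before their values were seen, on lists written after the first results.

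Gene families outside the gut lists held single large changes. Among 48 keratins 7 rose and 2 fell on the arrays labelled cKO (8 and 2 adjusted over the list alone), led by Krt84, a hair keratin (2.96 ± 0.19, from a level of 5.75), and Krt7, a keratin of simple epithelia (1.19 ± 0.10). The higher count was 4 without control 1, control 2, cKO 1 or cKO 3, the lower count was 0 without control 2 and 1 without control 3, cKO 1 or cKO 3, and the list did not pass (median −0.01, −0.05 to −0.004 with 1 array left out, mean 0.09, camera adjusted p = 0.522). Among 23 claudins, the tight junction proteins, Cldn8 rose by 2.62 ± 0.16; 2 rose and 1 fell (3 and 1 adjusted over the list alone; median −0.04, −0.08 to −0.01 with 1 array left out, mean 0.02, camera adjusted p = 0.902). The lower count was 0 without any 1 control array or without cKO 1, and 2 without cKO 2, and the higher count was 1 without control 1, control 2, cKO 1 or cKO 3, and 3 without cKO 2. Among 8 UDP-glucuronosyltransferases, which conjugate lipophilic compounds, Ugt2b36 rose by 1.44 ± 0.09 and Ugt2a3 fell by 3.15 ± 0.22. In all 2 rose and 1 fell (3 and 1 adjusted over the list alone; median −0.11, −0.19 to −0.03 with 1 array left out, camera direction higher, adjusted p = 0.819), and the higher count was 1 on leaving out any array. Among 11 aquaporins, the water channels, Aqp1 rose by 1.32 ± 0.17 and Aqp11 fell by 1.43 ± 0.14, also when adjusted over the list alone (median −0.09, −0.02 without control 2 or cKO 2 and 0 without control 3; camera adjusted p = 0.94), and the lower count was 2 without cKO 2.

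Few members of the remaining families passed on their own. Of 53 cytosolic ribosomal protein genes 50 had a change above 0 (median 0.14, camera adjusted p = 6.1e-06; adjusted p = 0.794 with an estimated correlation; fry adjusted p = 0.083), with 1 past the threshold alone, Rpl12, which was lost without control 1, control 3, cKO 1 or cKO 3 (adjusted p up to 0.106), and 2 passed without control 2. All 34 mitochondrial complex I genes had a change below 0 (median −0.18, camera adjusted p = 9.41e-05; adjusted p = 0.794 with an estimated correlation; fry adjusted p = 0.081), with 1 past it, Ndufv3, lost on leaving out any array (adjusted p up to 0.0941). Adjusted over the list alone 0 genes of both lists passed under limma. Of 39 proteasome genes 3 fell, also when adjusted over the list alone, and these were the immunoproteasome genes Psmb8, Psmb9 and Psmb10 (−0.95 ± 0.08, −0.96 ± 0.08 and −0.72 ± 0.08); the list did not pass (median 0.01, −0.03 to 0.03 with 1 array left out, mean −0.05, camera adjusted p = 0.94). Of 37 Hox genes 1 rose and 1 fell, with 1 and 0 adjusted over the list alone (median −0.06, −0.095 to −0.01 with 1 array left out, camera adjusted p = 0.819), and of 15 aminoacyl-tRNA synthetases 1 rose and 1 fell, also when adjusted over the list alone (median 0.01, −0.03 to 0.05 with 1 array left out, camera adjusted p = 0.819). Those calls were lost in several fits without 1 array: Hoxa3 without control 2, control 3 or cKO 3, Hoxc13 without any array but control 2, Vars without control 2 or control 3, and Wars without control 2, control 3 or cKO 3 (adjusted p up to 0.0991). The higher counts were 2 for Hox genes without cKO 2 and 2 for the synthetases without cKO 1.

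Because immunoproteasome genes moved with interferon-stimulated genes, it was asked whether the other genes of MHC class I antigen processing may do so. Of 12 measured, 7 (58.3%) were lower on the arrays labelled cKO and 0 higher, with 8 and 1 adjusted over the list alone (median −0.54, camera adjusted p = 8.84e-05; adjusted p = 0.169 with an estimated correlation). The lower count was 4 without control 1, 3 without control 3 and 5 without control 2 or cKO 3. It was 6 without cKO 1 and 7 without cKO 2. A majority called lower, with the camera shift past the threshold, had been set in advance to mark such a move, and both were met. The exact 95% binomial interval of 7 in 12, added after the value was seen and covering counting error only, runs from 27.7% to 84.8%. It therefore does not settle whether most such genes move. Members named after their values were seen were Psme1 (−0.79), Tapbpl (−0.91) and Tap1 (−0.78).

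The falls of Abcg5 and Abcg8, known targets of the LXR receptors, could reflect lower LXR activity. Of 11 other LXR targets 1 (9.09%) was lower, Lpcat3 (−0.70), and 1 higher, Mylip (0.84), both named after their values were seen (median −0.17, camera adjusted p = 0.131). Adjusted over the list alone, 4 were lower and 1 higher, at an unadjusted p under 0.05 these counts were 5 and 1, and the median was −0.42 without cKO 2. The exact 95% binomial interval of 1 in 11, which covers counting error only, reaches 41.3%. A share under 25% had been set in advance to argue against the explanation, but this interval, added after the value was seen, includes 25% and leaves the question open. Past the threshold over all genes, 2 were lower without control 1 or cKO 2, and the call of Mylip was lost without any 1 control array or without cKO 1.

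Pparg rose, so a rise of PPAR gamma targets could follow. Of 11 such targets 1 (9.09%) was higher, Txnip (1.03), and 1 lower, Cidec (−2.06), both named after their values were seen (median −0.12, camera adjusted p = 0.771), with the same interval as for LXR, and the question stays open. Adjusted over the list alone, 1 was higher and 2 lower, and 2 were lower without cKO 1. The median was −0.05 without control 2, −0.08 without cKO 1 and −0.02 without cKO 3.

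The 2580 genes can be set beside other splits of the 6 arrays. There are 10 splits into equal groups, of which 1, the real one, gave as many genes, and the highest of the others gave 0 under limma, with up to 874 genes at an unadjusted p under 0.05 against 5294 in the real one. With 10 splits no share under 0.05 can be reached. Each of the other splits holds arrays of both labels on each side. A real difference then adds to the spread within the groups, so their low counts were largely fixed in advance and lend the 2580 no support.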
